A study of Mus musculus with 10 samples.

How the data were processed

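RNA with poly(A) tails was sequenced from primary T cells and B cells of mouse spleen in which promoters of Pou2f1 had been targeted by CRISPR interference, a method in which a guide RNA directs a catalytically dead Cas9 to a promoter to repress it. Whether the cells of each sample came from separate animals or cultures, how the cells were selected and how long the guides acted are not given in the sources used here. The authors deposited 1 table of whole-number read counts per gene, in the layout that featureCounts writes, with 56893 genes and 10 columns. Per the submitters' processing notes, HISAT2 and featureCounts were used, and the genome builds hg38 and mm39 were named. The versions of these tools, the annotation release, the strand setting, the pairing of reads and the treatment of reads that map to several places are not given in the sources used here. Reads that fit several copies of a gene, or a gene and an overlapping partner, may therefore have been dropped or assigned to one of them. Cd247, Pou2f1 in T cells and some named genes with known near-identical copies are reported as uncertain. Copies and overlapping partners were not searched for across all named genes or gene lists. A gene without this mark may therefore be affected in the same way. Coordinates are printed as the deposited table gives them. The reference at hand was GENCODE M21 on GRCm38, where 48826 of the 56893 symbols were found but only 1348 of them with the same start, so it was used for the GC content of transcripts and for no coordinate.

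Columns were assigned to 5 groups by the labels, with 2 columns per group labelled as replicates. Before any comparison, the columns of each group were set against each other. In every group, all genes with reads matched a single count divided in one fixed proportion and rounded down, to within 1 read. The mean chi-square per gene between the columns of a group, over genes with 20 or more reads, was 0.00229 to 0.00283. On simulated data it was 0 for 1 library divided in this way and 2 for 2 independent libraries whose fragments were counted as read pairs, both over 16014 genes. The columns of a group differed by less than the sampling noise, so they were summed and counted as 1 sample. With 1 library per group, no comparison has a replicate check, and no p-value is given for any single comparison.

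The tests chosen before the data were examined (edgeR's quasi-likelihood test on 10 libraries, camera on gene lists and a block on the replicate number) assumed 2 libraries per group and were not used for the comparisons. In their place, summed counts were scaled by TMM factors over the 5 libraries (edgeR 4.0.16 in R 4.3.3), which lay between 0.979 and 1.021. Log2 fold changes were taken of scaled levels (CPM) after adding a prior of 1 read, not scaled to depth, among genes with at least 5 CPM in the higher group. A size rule of 1.5-fold or more took the place of a test. Among genes with a sum under 10 reads, 72 to 74.8% of the totals were even once the read lost by rounding was added back, as counting both reads of a pair would give. Exact conditional 95% intervals of fold changes and exact Poisson 95% intervals of levels were therefore computed on the reads divided by 2. Intervals and floors cover counting error only, since the libraries carry no molecular identifiers. A gene with no read was given a floor of 3 reads.

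Gene lists were also fixed beforehand. For each list with 5 or more members at 5 CPM, the median log2 fold change was placed among 10000 random lists of the same size, matched on expression in 20 bins. A list was named as standing apart when its median fell outside the range from the 2.5 to the 97.5 percentile, which describes these libraries and is not a test of the conditions. By chance 5% of lists fall outside. The rule for named genes was fixed as Pou2f1, Pou2f2, Pou2f3 and Pou2af1, the 8 genes with the largest and the 8 with the smallest log2 fold change at 5 CPM or more, without predicted genes and pseudogenes, and up to 4 members of each list that stood apart. Its conditions on FDR, on replicates and on p could not be applied, so genes were ordered by size, and members of a list by the size of their log2 fold change. For T against B cells the 5 members of each identity list with the highest level were named, and for the difference of the sgRNA-P1 effects the 8 genes with the largest difference. Some genes that the rule takes are not reported here. Genes named outside the rule, which were chosen after their values were seen, are Gm6560, Gm4149, Gm4202, Hspd1-ps3, the neighbours of Pou2f1, Srp54a, Srp54c, Gm2058, Gm12751, markers of other cells, the other class I genes, Cd79b, Jchain, Ms4a1, Cd36, Cd74, H2-Ab1, Hspd1, Apoe, Igkc, Gm28437 and Gm28661.

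A model over the 5 libraries was added after the columns had been found to be divided: edgeR's quasi-likelihood test with cell type and guide (either guide against mock) as terms, 2 residual degrees of freedom and Benjamini-Hochberg adjustment at 0.05. Its spread is that between these libraries around effects assumed equal in both cell types and for both guides, and the p-values say nothing about animals. DESeq2 1.42.0 and limma-voom (limma 3.58.1) were run with the same terms. Overlaps of the size rule between 2 guide comparisons were counted among genes at 5 CPM in the higher group of each, and set beside 100 simulations of unchanged groups. A smooth trend of log2 fold change on gene length and GC content (mgcv 1.9.3) was subtracted as a further alternative. Other alternatives were RLE, upper-quartile and total-read scaling, other filters on low counts, scaling within a cell type or within the 2 groups compared, a prior scaled to library size, leaving out receptor gene segments, and leaving out each column or library.

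The size rule and the common model were tested on simulated data with counts drawn at the real levels and depths. Of 50 genes changed 2-fold, the size rule found 100% in T cells with sgRNA-P1, 100% in B cells with sgRNA-P1, 96% in B cells with sgRNA-P2 and 98% between both guides. Of 50 genes changed exactly 1.5-fold it found 52%, 42%, 46% and 36% in the same order. These simulations held counting noise and no biological or preparation noise. Random lists of 20 genes were drawn from the real log2 fold changes of B cells with sgRNA-P1. Of these, 3% fell outside the range with no shift and 100% with a planted shift of -0.20. The common model found 75% of genes changed 1.5-fold and 98.5% of those changed 2-fold, with 3 false calls among 10760 genes, at an assumed dispersion of 0.01. The length and GC fit was also run on log2 fold changes of 9708 genes drawn from a normal distribution with a planted GC trend. It returned a planted list shift of -0.20 as -0.21 (SD 0.03 over 20 draws). No length trend was planted, so its removal was not tested.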

Results

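Gene expression was measured by poly(A) RNA sequencing in primary T cells and B cells from mouse spleen after CRISPR interference at Pou2f1. Pou2f1 encodes Oct-1, a POU-domain transcription factor that binds octamer motifs and is transcribed from alternative promoters. The 5 groups were mock-treated T cells, T cells with the guide labelled sgRNA-P1, mock-treated B cells, and B cells with the guides labelled sgRNA-P1 and sgRNA-P2, which were directed at the P1 and P2 promoters. The 2 columns deposited for each group differed by less than the sampling noise and were counted as 1 sample. The summed libraries held 71858511 reads in mock T cells, 39352816 in T cells with sgRNA-P1, 33842813 in mock B cells, 49066261 in B cells with sgRNA-P1 and 28118839 in B cells with sgRNA-P2. Single columns held 11337138 to 41310310 reads. With 1 library per group the differences below have no replicate check, and the intervals in brackets are 95% counting intervals of those libraries.

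Pou2f1 was lower in every library with a guide than in the mock library of the same cell type. Its level was 138 CPM [134 to 141] in mock T cells and 65.7 CPM [62.2 to 69.4] in T cells with sgRNA-P1. In B cells it was 157 CPM [151 to 163] in mock, 91.4 CPM [87.6 to 95.3] with sgRNA-P1 and 86.8 CPM [82.1 to 91.9] with sgRNA-P2. The level left was 47.8% of mock in T cells [44.9 to 50.8], 58.2% in B cells with sgRNA-P1 [55 to 61.6] and 55.3% in B cells with sgRNA-P2 [51.7 to 59.2]. The gene spans 165692723 to 165830247 on the minus strand of chromosome 1 in the deposited coordinates, with 20 merged exon blocks. The table counts reads over the whole gene, so transcripts from P1 and P2 cannot be separated in it. Its 3' end, from 165692723 to 165704846, is shared with Cd247, a gene of the opposite strand that was at 313 CPM in mock T cells and 0.415 CPM in mock B cells, so the T cell values of Pou2f1 are uncertain.

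**Figure D1:**
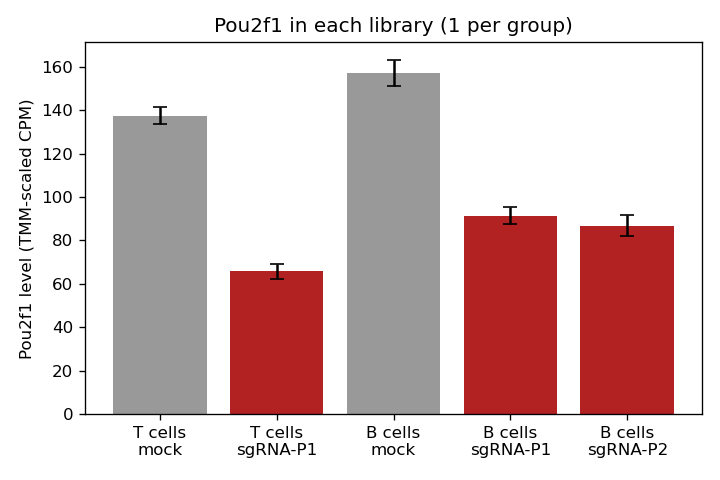
TMM-scaled Pou2f1 level in CPM (vertical axis) in the 5 libraries, 1 per group, with mock libraries in grey and guide libraries in red. Error bars are 95% counting intervals, and the guide libraries lie between 65.7 and 91.4 CPM against 138 and 157 CPM in mock.

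The relatives of Pou2f1 did not share its pattern. Pou2f2, which encodes the lymphoid factor Oct-2, stood at 58.8 CPM in mock T cells and 339 CPM in mock B cells. Its log2 fold change against mock was -0.00 in T cells [-0.11 to 0.10], 0.10 in B cells with sgRNA-P1 [0.05 to 0.14] and 0.04 in B cells with sgRNA-P2 [-0.01 to 0.10]. Pou2af1, the B cell coactivator of both factors, was at 20.8 CPM in mock T cells and 623 CPM in mock B cells. Its log2 fold change was 0.19 in T cells [0.02 to 0.36], 0.04 with sgRNA-P1 in B cells [-0.00 to 0.07] and 0.00 with sgRNA-P2 [-0.04 to 0.04]. No library held a read of Pou2f3, for which 3 reads would be 0.0414 to 0.107 CPM.

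The mock libraries of both cell types were compared first, as a check of the cell labels. All 21 genes of the T cell identity list were at least 2-fold higher in mock T cells, with a median level of 462 CPM against 0.207 CPM in mock B cells. All 21 genes of the B cell identity list were at least 2-fold higher in mock B cells, with a median of 1040 CPM against 0.746 CPM. Among T cell genes, the kinase gene Lck (799 against 46.2 CPM) and the co-receptor gene Cd4 (654 against 0.267 CPM) were higher in T cells. Thy1 had 604 CPM in T cells and 1 read in B cells, a log2 ratio of 13.32. Its interval starts at 11.43 and is open above, because 1 read divided by 2 was rounded down to no fragment. The receptor constant gene Trbc2 had 721 CPM in T cells and no read in B cells, and so was at least 8110-fold higher against a floor of 3 reads. Among B cell genes, Ighm (5620 against 340 CPM), Ighd (2960 against 6.42 CPM), Cd22 (1590 against 6.9 CPM) and Cd37 (1460 against 270 CPM) were higher in B cells. Across the table, 1993 genes were at least 1.5-fold higher in T cells and 2003 in B cells, of 10806 at 5 CPM or more. Pou2f1 itself was slightly lower in T cells, with a log2 fold change of -0.19 [-0.26 to -0.12], which is uncertain because of the segment shared with Cd247.

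T cells with sgRNA-P1, the guide directed at the P1 promoter, were compared with mock T cells. The libraries were close: 86.7% of 10001 genes lay within 1.1-fold, and 11 were 1.5-fold or more apart, 6 higher and 5 lower, where counting noise alone put 1 of 9807 unchanged genes past that size in simulated libraries. Pou2f1, with a log2 fold change of -1.06 [-1.15 to -0.98], ranked 3 from the lowest. Below it stood Gm6560, a predicted gene at 39.3 CPM in mock and 6.1 CPM with the guide, and H2-Q10, a class I histocompatibility gene, at 27.2 and 7.87 CPM. The other named genes past 1.5-fold and lower were Maml3, a Notch coactivator gene (log2 fold change -0.63 [-0.95 to -0.34]), and Cdc42ep4 (-0.60 [-0.98 to -0.24]). The only named gene past 1.5-fold and higher was Srp54b, a copy of the signal recognition particle gene Srp54, at 15.3 CPM against 1.62 CPM (3.23 [2.85 to 3.69]). H2-Q10 and Srp54b have near-identical copies in the genome, so their counts are uncertain.

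Below the 1.5-fold rule, the next genes in order were mostly at low levels. Higher were Rps27rt, a retrocopy of a ribosomal protein gene and so uncertain (0.55), Smim26 (0.50), Rita1 (0.50), the respiratory chain assembly gene Uqcc5 (0.47), Zfp383 (0.44), Cdkl3 (0.39) and Malat1. Malat1, an abundant nuclear noncoding RNA, was at 2894 CPM with the guide and 2157 CPM in mock, a log2 fold change of 0.42 [0.41 to 0.44]. Lower were Map1lc3a, which encodes an autophagosome protein (-0.56), the clock gene Per3 (-0.54), Zfp719 (-0.53) and the cilium gene Rpgrip1l (-0.52).

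Of 25 gene lists with 5 or more members, 3 stood apart in T cells. Cytosolic ribosomal protein genes had a median log2 fold change of 0.04, above the random range of -0.04 to -0.00, with 16 of 26 higher, among them Rps14 (0.15), Rps19 (0.14) and Rplp1 (0.12). The list of ATF4 targets and amino acid stress genes had a median of -0.08, below the range of -0.07 to 0.03, with 9 of 11 members lower. In it, Sesn2 had -0.45 [-0.82 to -0.08], Slc7a11 -0.28 [-0.58 to 0.01], Atf4 itself -0.10 [-0.15 to -0.05] and Psat1 -0.10 [-0.24 to 0.04]. The oxidative phosphorylation list, with a median of 0.01 at the edge of its range, had 12 members higher and 10 lower. Cox5a (-0.18), Ndufa1 (0.15), Cox7a2 (0.14) and Ndufa2 (0.12) were its largest values, and the interval of each of the latter 3 reached 0. T cell identity genes (median -0.02), naive and memory genes (-0.02), activation and effector genes (-0.01) and interferon response genes (-0.01) lay within their ranges. No member at 5 CPM or more of these 25 lists reached 1.5-fold in T cells. After a length and GC trend was subtracted, the ribosomal protein median was 0.02 and the oxidative phosphorylation median was -0.00. Of 7180 genes at 20 CPM or more, 6 passed 1.5-fold.

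Cd247, which encodes the zeta chain of the T cell receptor complex, overlaps the 3' end of Pou2f1 on the opposite strand. It was at 313 CPM in mock T cells and 271.8 CPM with sgRNA-P1, a log2 fold change of -0.20 [-0.25 to -0.16]. Without a stated strand setting, reads of Cd247 and Pou2f1 in the shared segment cannot be separated, so this value is uncertain, as are those of Pou2f1 in T cells. Other expressed genes within 500 kb differed by less than 0.10 on the log2 scale in T cells, with Rcsd1 at -0.06, Dcaf6 at -0.03, Mpc2 at 0.09, Creg1 at 0.06, Tada1 at -0.09 and Pogk at 0.05.

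In B cells with sgRNA-P1, mitochondrially encoded mRNAs were higher than in mock and cytosolic ribosomal protein mRNAs were lower. All 10 mitochondrial mRNAs listed were higher, with a median log2 fold change of 0.72 against a random range of -0.08 to 0.11, and 7 passed 1.5-fold. The largest was mt-Nd6 (1.40 [1.34 to 1.45]), followed by mt-Co2 (0.80 [0.69 to 0.91]), mt-Nd2 (0.76 [0.74 to 0.77]) and mt-Atp6 (0.74 [0.62 to 0.86]). Mitochondrial genes took 3.79% of reads with sgRNA-P1 and 2.54% in mock. Copies of mitochondrial sequence lie in the nuclear genome, so single mitochondrial genes are uncertain. All 26 ribosomal protein genes were lower, with a median of -0.20 against a range of -0.03 to 0.07, led by Rps19 (-0.52), Rps14 (-0.41), Rplp1 (-0.39) and Rps2 (-0.36), each 1.29 to 1.43-fold below mock.

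The nuclear genes of oxidative phosphorylation were also lower in this library, 20 of 22 of them, with a median of -0.15 against a range of -0.07 to 0.06. Ndufa2 (-0.54 [-0.72 to -0.35]), Cox7a2 (-0.40 [-0.59 to -0.21]), Cox4i1 (-0.34 [-0.42 to -0.25]) and Ndufa1 (-0.31 [-0.57 to -0.06]) led them. Genes of MHC class II presentation had a median of -0.09 against a range of -0.06 to 0.10, with 10 of 12 lower. Their median was -0.02 after a length and GC trend was subtracted. H2-DMb1 (-0.18), Ifi30 (-0.16) and H2-Eb1 (-0.14) were lower and H2-Oa was higher (0.12), each with an interval that excludes 0. These were the 4 lists of 25 that stood apart. The B cell identity list (median 0.04, 13 of 21 higher) lay within its range, as did genes with known octamer sites in their promoters (0.05, 5 of 8 higher), activated and germinal centre genes (0.05) and plasma cell genes (-0.08).

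Among single genes, Pou2f1 (-0.78 [-0.86 to -0.70]) ranked 6 from the lowest of 10067. The libraries were further apart than in the other guide comparisons with mock. Here 65.1% of genes lay within 1.1-fold, against 86.7% in T cells with sgRNA-P1 and 79.9% in B cells with sgRNA-P2. By the size rule 48 genes were higher and 26 lower, where counting noise alone put 4 of 9819 unchanged simulated genes past it. Srp54b was higher (1.88 [1.27 to 2.60]), as were the zinc finger genes Zfp975 (1.12 [0.73 to 1.56]), Zfp54 (0.999 [0.58 to 1.43]) and Zfp931 (0.83 [0.36 to 1.33]), the membrane glycoprotein gene Gpm6b (0.95 [0.49 to 1.40]) and Depdc1a (0.90 [0.44 to 1.41]). Lower were Trp53rkb (-0.96), the complex I gene Ndufs5 (-0.80), Actr3b (-0.74), the mitochondrial ribosomal protein gene Mrpl55 (-0.71), H2-Q10 (-0.69), the immunoglobulin segment Ighv14-2 (-0.69) and the tubulin cofactor gene Tbcc (-0.69). Except for Pou2f1, these genes were at 15.3 CPM or less in both libraries. Of 7215 genes at 20 CPM or more, 15 passed the rule, 13 higher and 2 lower. Log2 fold changes were lower in genes of higher GC content (Spearman's rho across genes -0.50). After a length and GC trend was subtracted, 42 genes passed 1.5-fold, 25 higher and 17 lower. Before it 69 passed among genes with a GC content.

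**Figure D2:**
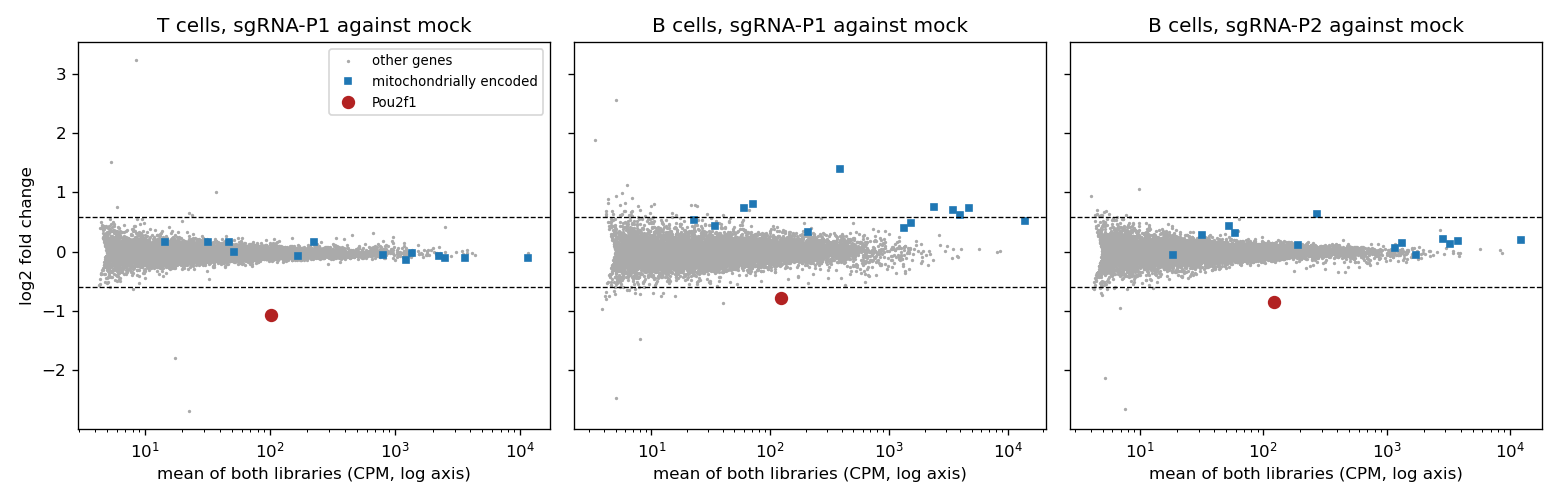
Log2 fold change against mock (vertical axis) by the mean level of both libraries in CPM (log axis), 1 point per gene at 5 CPM or more, in the 3 guide comparisons. Red marks Pou2f1 (-1.06, -0.78 and -0.85), blue squares mark mitochondrially encoded genes, and dashed lines mark 1.5-fold.

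In B cells with sgRNA-P2, the same 4 lists stood apart of 25, at smaller medians, in a comparison with the same single mock library, so that it is not independent of the first. All 26 ribosomal protein genes were lower, with a median of -0.10 against a range of -0.02 to 0.03, led by Rps2 (-0.26), Rpl37 (-0.19), Rplp1 (-0.19) and Rps14 (-0.19). Mitochondrially encoded mRNAs had a median of 0.20 against a range of -0.04 to 0.04, with 9 of 10 higher, led by mt-Nd6 (0.64 [0.58 to 0.70]), mt-Atp6 (0.43 [0.29 to 0.57]), mt-Co2 (0.32 [0.19 to 0.46]) and mt-Co3 (0.28 [0.09 to 0.46]). Oxidative phosphorylation genes had a median of -0.07 with 17 of 22 lower, among them Ndufa2 (-0.27 [-0.48 to -0.07]), Ndufv1 (-0.17 [-0.31 to -0.04]) and Cox4i1 (-0.14 [-0.24 to -0.04]), while the interval of Ndufa1 (-0.15) reached 0. MHC class II genes had a median of -0.04 with 8 of 12 lower, with Ifi30 at -0.15, H2-Aa at -0.06, H2-DMb1 at 0.06 and H2-Oa at 0.10, and a median of -0.01 after a length and GC trend was subtracted. The B cell identity list had a median of 0.00 and the octamer-site list 0.03, both within their ranges.

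Pou2f1 (-0.85 [-0.95 to -0.76]) ranked 4 from the lowest of 10071 genes with sgRNA-P2. By the size rule 13 genes were higher and 14 lower, and 79.9% of genes lay within 1.1-fold. Lower were H2-Q10 (-0.95 [-1.38 to -0.52]), Coq4 of coenzyme Q synthesis (-0.72 [-1.23 to -0.22]), Tmem256 (-0.62), Marchf9 (-0.62), Ccdc138 (-0.62), Ighv14-2 (-0.61) and the channel gene Hcn3 (-0.61). Higher were Hic2 (0.69 [0.24 to 1.18]), Diras2 (0.65), Zfp174 (0.64), Dcbld1 (0.62) and the immunoglobulin segment Ighv5-12 (0.60), with the retrovirus restriction gene Fv1 (0.58) and the receptor gene Pira2 (0.56) just under 1.5-fold. This was the shallowest library, and counting noise alone put 11 of 9826 unchanged simulated genes past the rule. At 20 CPM or more 2 genes passed it, Pou2f1 and mt-Nd6. With a length and GC trend subtracted, 16 genes were higher and 9 lower by the rule, among genes with a GC content.

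Both guides were compared directly in B cells, without the mock library. Pou2f1 differed by 0.07 [-0.03 to 0.17] on the log2 scale, a difference not detectable at this depth. Mitochondrially encoded mRNAs were higher with sgRNA-P1 than with sgRNA-P2, 10 of 10, at a median of 0.48 against a range of -0.06 to 0.08, with mt-Nd2 (0.81), mt-Nd6 (0.76), mt-Cytb (0.55) and mt-Nd1 (0.50) leading. Ribosomal protein genes were lower, 25 of 26, at a median of -0.09, led by Rps19 (-0.33), Rps14 (-0.22), Rps3 (-0.21) and Rplp1 (-0.21). Oxidative phosphorylation genes had a median of -0.12 with 18 of 22 lower, led by Cox7a2 (-0.37), Ndufa2 (-0.26), Uqcrfs1 (-0.21) and Cox4i1 (-0.20). NF-kB target genes had a median of -0.08 with 8 of 12 lower, of which Bcl2a1d (-0.32), Traf1 (-0.13) and Tnf (-0.10) had intervals that reach 0 and Nfkbie (-0.09 [-0.17 to -0.01]) did not. Bcl2a1d has near-identical copies, so its count is uncertain. These were the 4 of 24 lists that stood apart. Log2 fold changes between the guides were lower in genes of higher GC content (Spearman's rho across genes -0.45). With a length and GC trend subtracted, the medians were 0.33 for mitochondrially encoded mRNAs, -0.06 for ribosomal protein genes and -0.09 for oxidative phosphorylation genes. The NF-kB median was not computed after the trend.

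Between the guides 72.7% of genes lay within 1.1-fold. By the size rule, 28 genes were higher with sgRNA-P1 and 12 lower, of 10068, where counting noise alone put 7 of 9806 unchanged simulated genes past it. Higher were Srp54b (1.29), Ccdc18 (0.91), Zfp975 (0.81), the muscle protein gene Neb (0.78), Gpm6b (0.77) and Zfp948 (0.71). Lower were Myef2l (-0.87), the adenylyl cyclase gene Adcy6 (-0.67), the immunoglobulin segment Ighj3 (-0.67), Amz1 (-0.64), Cep19 (-0.62) and the nuclear receptor gene Nr2f6 (-0.62), with Zfp128 (-0.53) and Ighv5-12 (-0.53) under 1.5-fold. At 20 CPM or more 6 genes passed the rule, and after a length and GC trend was subtracted 24 did, 14 higher and 10 lower, against 36 before it among genes with a GC content.

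The effect of sgRNA-P1 in T cells was then set against its effect in B cells. The effects differed by 1.5-fold or more at 119 of 9140 genes, 58 with the larger log2 fold change in T cells and 61 in B cells, and at 81 and 45 genes when libraries were scaled by total reads. How many genes counting noise alone would put past this size was not simulated for this difference. Pou2f1 had -1.06 in T cells and -0.78 in B cells, a difference of -0.28, and the intervals of both values do not overlap. They cover counting error only, and the difference is uncertain because of the segment shared with Cd247. The largest differences, leaving out predicted genes and pseudogenes, were those of Srp54b (3.23 in T cells and 1.88 in B cells), mt-Nd6 (0.16 and 1.40), Tmed2b (-0.44 and 0.68) and H2-Q10 (-1.78 and -0.69). Zfp54 (-0.08 and 0.999), Ndufs5 (0.17 and -0.80), Zfp125 (-0.49 and 0.41) and Zfp931 (-0.06 and 0.83) followed. Ribosomal protein genes had a median of 0.04 in T cells and -0.20 in B cells, and mitochondrially encoded mRNAs -0.05 and 0.72, or -0.12 and 0.55 after a length and GC trend was subtracted. With 1 library per group these differences were not tested, and at 20 CPM or more 35 genes passed 1.5-fold.

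Correlations between the guide effects were computed over 8924 genes at 5 CPM or more in every library. In B cells the log2 fold changes of both guides had Pearson's r = 0.56 and Spearman's rho = 0.55 across genes, which are not independent replicates. Both share the mock library, and 100 simulations of unchanged groups gave r = 0.516 (SD 0.0115). The covariance was 0.00977 against 0.00439 in the simulations, a difference of 0.00538, and part of this excess may come from the single mock library, which could not be divided. Among these 8924 genes, Pou2f1 and Tmem256 were lower by 1.5-fold with both guides and mt-Nd6 was higher. In a wider set chosen after the data had been seen, the 10009 genes at 5 CPM or more in the higher group of each B cell comparison, 6 were lower with both: Pou2f1, H2-Q10, Ighv14-2, Tmem256, Hcn3 and the predicted gene Gm2058. Simulated unchanged groups with a shared mock library gave 0.23 on average and 2 at most, from counting noise alone, and independent lists would share 0.0364. Higher with both were mt-Nd6, Diras2 and the predicted gene Gm12751, where the simulations gave 0.32 on average and 2 at most and independent lists would share 0.0238. Between T cells and B cells with sgRNA-P1, which have separate mock libraries, r was -0.02 and rho -0.02. Of the 8924 genes, Pou2f1 and Gm6560 were lower in both and 0 were higher in both. Of the wider set of 9140 genes, Pou2f1, H2-Q10 and Gm6560 were lower in both (0.0115 expected of independent lists) and Srp54b was higher in both (0.0159 expected). T cells with sgRNA-P1 and B cells with sgRNA-P2 had r = -0.04, with Pou2f1 lower in both and Gm4149 higher in both of the 8924 genes. Of the wider set of 9139 genes, Pou2f1 and H2-Q10 were lower in both (0.00328 expected) and Gm4149 was higher in both (0.00219 expected). In all 3 guide comparisons, Pou2f1 and H2-Q10 were lower by 1.5-fold of the wider set of 9114 genes, Pou2f1 alone of the 8924, and 0 were higher. Pou2f1 was the gene targeted in every guide library, so its place in these overlaps was built into the design. H2-Q10 and Srp54b have near-identical copies and uncertain counts. The counts expected of independent lists therefore do not test a shared guide effect.

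A guide effect common to both cell types was tested with edgeR's quasi-likelihood test over the 5 libraries. Of 10758 genes, 2 were called after Benjamini-Hochberg adjustment. Pou2f1 fell, with a log2 fold change of -0.91 (SE 0.06) and an adjusted p of 1.1e-05 by edgeR, and was lower in 3 of 3 guide libraries. Malat1 rose by 0.38 (SE 0.05, adjusted p = 0.0417 by edgeR) and was higher in 3 of 3, at 2894, 2868 and 3066 CPM in the guide libraries against 2157 and 2368 CPM in mock. At an unadjusted p under 0.05 there were 228 genes by edgeR, 234 by limma-voom and 55 by DESeq2. All of these counts lie below the share of 0.05 of the 10758 genes that chance alone would give. limma-voom called the same 2 genes and DESeq2 called H2-Q10 as well. Pou2f1 stayed lower when each library was left out in turn. Its log2 fold change was -0.813 without mock T cells, and the same without T cells with sgRNA-P1. It was -1.045 without mock B cells, -0.955 without B cells with sgRNA-P1 and -0.909 without B cells with sgRNA-P2. Without 1 of the T cell libraries the guide effect came from B cells alone, and without mock B cells from T cells alone. Fits of these kinds therefore do not test a common effect, for Pou2f1 or for Malat1. Malat1 had an edgeR adjusted p of 0.686 without mock T cells, 0.621 without T cells with sgRNA-P1, 0.758 without mock B cells, 0.232 without B cells with sgRNA-P2, 2.62e-05 without B cells with sgRNA-P1, 0.0746 with scaling by total reads, and 3.37e-09 with no filter on low counts. The p-values measure the spread between these 5 libraries, which may be technical.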

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

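The subtraction of a length and GC trend was added after the data had been seen, with its bound set before its result, and the spreads set against the H2-Q10 and Srp54b values were added after those values had been seen.

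In B cells with sgRNA-P1, mitochondrially encoded mRNAs were higher (median log2 fold change 0.72) and cytosolic ribosomal protein mRNAs lower (-0.20) than in mock. The tables argue against a length and GC trend as the whole cause, since the ribosomal protein median was -0.167 (SE 0.023) after the trend was subtracted, although the trend took 26.3% of the deviance over all genes and moved the mitochondrial median to 0.55. They also argue against the fall of Pou2f1 by itself as a cause in any lymphocyte, since in T cells the ribosomal protein median was 0.036 (SE 0.021), provided that Pou2f1 was lower there as its count was (-1.06, uncertain because of the segment shared with Cd247). On simulated data only the removal of a GC trend was tested, not that of a length trend. Both SEs come from resampling the genes of the list and hold no spread between libraries. Both arguments therefore hold for these libraries only. A response to lower Pou2f1 confined to B cells stays open, although with sgRNA-P2 Pou2f1 was lower by about as much (-0.85) and the mitochondrial median was 0.20. A difference in cell state or in the preparation of 1 library also stays open, because each group holds a single library, so the shift may not come from the guide.

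H2-Q10 was lower in T cells with sgRNA-P1 (27.2 to 7.87 CPM), and lower by 1.5-fold in both B cell comparisons. If reads had moved to near-identical class I genes, these would have gained about what H2-Q10 lost. The other 15 class I genes together gained -7.88 times the loss, going from 8016.2 to 7864.1 CPM, which lay below the bound set beforehand by less than its spread of 12.4 times. A move of reads therefore cannot be told apart from a change in H2-Q10 itself, since the loss of 19.3 CPM is small beside the spread of 239 CPM of those genes. A different genetic background of the animals may also alter such counts, which was not tested because a count table holds no variants.

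Srp54b was higher with sgRNA-P1 in T cells (1.62 to 15.3 CPM) and in B cells (1.42 to 5.31 CPM). If reads had moved from its copies, Srp54a and Srp54c would have lost about what Srp54b gained in T cells. Their summed loss was 0.0745 times the gain with a spread of 0.126 times, which is far from a loss that matches the gain but below the bound set beforehand by no more than that spread. Reads that were dropped because they fit several copies are not in the table, so a change in which reads could be placed cannot be told apart from a change in Srp54b. A genetic difference between animals may have the same effect and was not tested.

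The predicted gene Gm4202 and the pseudogene Hspd1-ps3 differed from mock in opposite directions with sgRNA-P1 in the 2 cell types, each past 1.5-fold. Gm4202 had a log2 fold change of 1.01 in T cells and -0.87 in B cells. Hspd1-ps3 had 1.51 in T cells and -1.47 in B cells, and its parent gene Hspd1 had -0.02 and 0.05. In B cells with sgRNA-P2, against the same mock library, Gm4202 had 0.55 and Hspd1-ps3 had 0.26. With 1 library per group the differences were not tested, and the reads of such genes are uncertain.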

How the results depend on the processing

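Alternatives chosen after seeing the data were scaling by total reads, the filter at 20 CPM, the length and GC trend, the sets without mitochondrial and ribosomal protein genes, the overlaps over genes listed in both comparisons, the prior scaled to library size, and every setting of the common model. Of 185 values that answer a comparison, 140 stayed within their limits, 45 moved and 0 reversed. Of 1948 values of single genes and lists, 1934 stayed, 14 moved and 0 reversed. Pou2f1 stayed within its counting interval in every setting except in B cells with sgRNA-P1 after the length and GC trend (-0.88). Leaving out a column is no check, since it must return nearly the same fold. The filter at 20 CPM likewise cannot change the fold of a gene or the median of a list. A count of genes could only stay or move, so 0 reversed is no result for counts. Many of the values that stayed were therefore fixed beforehand, and the tallies of 185 and 1948 values do not measure stability. No paired analysis was possible because the 2 columns of each group are 1 library, so the replicate numbers pair nothing. For the same reason the planned DESeq2, limma-voom and block alternatives of single comparisons were not run, nor was camera, to which the planned correlation and prior count alternatives belong.

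Counts of genes past 1.5-fold moved with the filter on low counts. They are given for T cells with sgRNA-P1, B cells with sgRNA-P1, B cells with sgRNA-P2 and between the guides. With no filter they were 6560, 6220, 7124 and 6413, with 13517 between mock T and B cells and 6994 for the difference of the sgRNA-P1 effects. At 1 CPM in 2 libraries they were 763, 831, 853 and 1082, with 1764 for the difference of effects. At 1 CPM, 243 of the 763 genes, 272 of the 1082 and 293 of the 1764 had no read in a pair of libraries, and the fold of that pair came from the prior of 1 read, which was not scaled to depth. The other looser counts held no such gene, and the cause of their size was not tested. With a prior scaled to library size the counts were 7520, 7916, 7181, 7674, 14980 and 6917 with no filter, and 559, 897, 865, 869 and 1582 for the same comparisons at 1 CPM. The balance of higher and lower genes at 1 CPM turned with the prior, from 504 and 259 to 228 and 331 in T cells and from 411 and 671 to 506 and 363 between the guides, so no direction is read from it. In the main counts the scaled prior gave 11, 75, 28 and 42, and it moved no named gene of these 4 comparisons by more than 0.009 on the log2 scale. At 20 CPM the counts were 6, 15, 2 and 6, with 2524 between mock cells and 35 for the difference of effects, and with the scaled prior the same except for 7 between the guides and 2525 between mock cells. After a length and GC trend was subtracted, 42 genes passed in B cells with sgRNA-P1 and 24 between the guides, against 69 and 36 before it among genes with a GC content, and 40 and 22 of them were among the main 74 and 40. Without mitochondrial and ribosomal protein genes the counts were 10, 64, 26 and 38. The correlation of both guides in B cells was 0.46 at 1 CPM (0.494 with the scaled prior) and 0.60 at 20 CPM, and the cause was not tested.

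The common model called 1 gene with scaling by total reads and 9 with no filter, against 2 in the main model, and the cause was not tested. Without 1 of the T cell libraries the model estimates the guide effect in B cells alone, and without mock B cells in T cells alone. Without 1 of the B cell guide libraries it still rests on both cell types, with 1 residual degree of freedom. Counts of called genes from these fits are therefore not set beside the main model. Depth limits genes near 5 CPM, such as Hcn3 in B cells with sgRNA-P2, with an interval of -1.18 to -0.10.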

Other observations

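The comparison of the columns within a group was chosen after the columns had been seen to be nearly proportional.

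Lists of markers of other spleen cells had medians of 1.21 CPM or less in every library, for monocytes and macrophages, neutrophils, dendritic cells, NK and innate lymphoid cells, erythroid cells, platelets and stroma. Single members were higher. In mock T and mock B cells, Ccr7 of the dendritic cell list was at 508 and 422 CPM, Pecam1 of the stroma list at 236 and 333 CPM, Itgb3 of the platelet list at 166 and 46.2 CPM, and Apoe of the macrophage list at 9.71 and 204 CPM. Cst3 (24.9 and 70.3 CPM), Bst2 (38.7 and 20.3 CPM), Ccr2 (34.8 and 0.504 CPM) and Eomes (32.4 and 0 CPM) were among the others above 20 CPM. T or B cells themselves are known to express several of these genes, among them Ccr7. In mock T cells Ighm was at 340 CPM while Igkc was at 2.65 CPM. Genes with known octamer sites in B cells included Ms4a1 (0.18 with sgRNA-P1 and 0.06 with sgRNA-P2), Igkc (0.13 and 0.08), Cd36 (0.17 and 0.09), Cd79b (-0.12 and -0.05) and Jchain (-0.03 and -0.09). Cd74, the invariant chain of MHC class II, had -0.01 and 0.03 while its partners H2-Aa (-0.09 and -0.06) and H2-Ab1 (-0.10 and -0.02) were slightly lower.

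The hypothesis that each group holds 2 separately counted libraries was tested by the chi-square per gene between its columns, which would be about 1 or more for separate libraries. The largest value over the 5 groups was 0.00283, against 3.95 to 705 between groups, which argues against separate libraries. How the columns came to be divided is not given in the sources used here. If they were taken as replicates, edgeR's quasi-likelihood test would call 1907 genes in T cells with sgRNA-P1, 4676 and 1348 in B cells with sgRNA-P1 and sgRNA-P2, and 3211 between the guides, of 16414 tested. These counts measure counting precision and no spread between samples.

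Without the library of B cells with sgRNA-P2, the common model called Pou2f1, Srp54b, Gm28437 and Gm28661, of which the latter 2 are predicted genes that were at 29.3 and 23.5 CPM in T cells with sgRNA-P1 against 18.9 and 16.3 CPM in mock T cells. In B cells they were at 32.8 and 36.0 CPM with sgRNA-P1 and 24.1 and 23.1 CPM in mock. Whether these 2 genes share reads with other genes was not examined, so their values are uncertain.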
